A study of Xenopus laevis with 14 samples.

How the data were processed

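RNA-seq of animal caps and FLAG ChIP-seq of caps injected with tagged prdm12 made up 14 samples, of which 10 were RNA libraries in 5 groups of 2. RNA was poly-A selected and libraries were made with a kit that does not keep strand, per the labels' protocols. Bowtie2, Bowtie, edgeR and HOMER are named in the submitters' processing notes, without versions or the step each was used for. The gene counter, its settings, the aligner of each assay and the genome builds were not given in the sources used here.

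The expression values were deposited as a normalized signal per gene, which is a read count divided by 1 factor per library, as the values themselves show. In each library 100% of the values were whole multiples of the value of 1 read, within 0.05 of that step. The deposited table had 19926 lines, of which 5 were the special counters that HTSeq-count writes and were kept out of library sizes and tests. The other 19921 were Ensembl genes named by Xenopus tropicalis identifiers on GL scaffolds, 15688 of them with a symbol, and 3210 were 0 in every library. Reads of the homeologous gene copies of Xenopus laevis therefore share 1 line, and close paralogs such as krt12 and KRT12 and overlapping genes are uncertain. Of the read records that the counter tallied, between 7.53% and 11.1% lay in no feature and between 0.0566% and 0.103% were ambiguous. Unaligned reads were not among these records, so the share of sequenced reads that aligned is not known here. Records not aligned uniquely were 44.0% and 34.3% in the wild-type libraries, 27.7% and 26.4% with noggin and retinoic acid, 27.5% and 27.9% with prdm12, 25.8% and 23.8% with VP16 and 34.1% and 34.2% with engR. Reads are not independent molecules, so counting intervals cover counting error only.

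Peak positions were called with HOMER against pooled inputs, the same for both lists, at 4-fold over input and over the local 10000 bp, a Poisson p of 0.0001 and a false discovery rate of 0.001, per the file headers. Each list came from 1 ChIP library. The score column of the deposited peak lists was 1 in every line, so peaks could not be ranked by height. Of the putative peaks, 21.1% and 29.2% were removed by the comparison with input, per the file headers. Peaks lay on scaffolds named by number in a build that was not given in the sources used here, and no gene coordinates of that build were used, so peaks were not assigned to genes.

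Libraries were grouped by their titles. The wild-type columns of the table carry a code and were matched to the untreated caps because every other column names its construct. Replicate 1 of engR has a title that names engR and a treatment that names VP16. The labels do not say that replicates came from separate clutches or cultures, so p-values measure only the spread between these samples, which may be technical.

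Groups, comparisons, tests, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The main test was limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(value + 1) of the 12937 genes with a mean of at least 10. All 10 libraries entered 1 fit with group as the only term (5 residual degrees of freedom, 3.17 prior), two-sided, with Benjamini-Hochberg adjustment in each of 7 comparisons and a threshold of 0.05. Every adjusted p given for a gene is from this test, except where limma with the replicate number as a block is named. Gene lists with at least 5 measured members were tested with camera at a correlation of 0.01, adjusted over 20 lists, and again with an estimated correlation and with fry. The lists hold 519 distinct symbols, gata3 stands in the epidermal and the flanking list and foxa2 in the endodermal and the flanking list, and prdm12 belongs to the V1 list.

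The rule for named genes took, in each comparison, up to 10 called genes per direction with the largest fold change, a symbol and no overlap between the libraries of the groups. It also took up to 4 members of each list with the smallest p, and prdm12, en1, dbx1, nkx6-1 and nkx6-2 in every comparison. The text names a part of these genes. For genes with 1 to 3 reads in a group, the ratio of recovered reads is given with its 95% counting interval.

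Alternatives were pseudocounts of 0.25 and 4, no filter and a mean of at least 50, quantile and median ratio scaling, no intensity trend, library weights, a fold of at least 2, the 2 compared groups alone and the replicate number as a block. The labels do not say what a replicate number marks. Differences between replicates 1 and 2 correlated across genes at 0.22 to 0.79 in all 10 pairs of groups, and the second principal component of the 8 neuralized libraries (27.1% of variance) was lower in replicate 2 of each of the 4 groups. The numbers were therefore taken to pair the libraries, a decision made from the data after counts with the block had been seen. The main test stayed without the block, and blocked values are given where they change a call or move a count by over 1.5 times. edgeR 4.0.16 and DESeq2 1.42.0 were run on recovered reads. Each library was left out in turn. A group then left with 1 library is assumed to vary like the others. DESeq2, edgeR with the block, the V1 list without prdm12, and part of the alternatives for construct agreement and reversal were chosen after the data had been seen. Chance values for the construct comparisons came from 100 simulations of unchanged groups against the same control libraries, repeated in the matching design, with and without the block, for each library left out. Peaks were compared with bedtools 2.31.1 at an overlap of at least 1 bp and with 100 random placements within scaffolds. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

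The tests were tried on 5 simulated data sets of 12937 genes, with 200 genes changed in the prdm12 group of each. Gene means of the noggin and retinoic acid libraries were given to all 10 libraries at their own depths. No other difference between groups and no shared effect of replicate number was simulated. limma recovered 1.2% of genes changed 2-fold, 29.6% at 4-fold, 67.2% at 8-fold and 85.6% at 16-fold, with 6.90% false calls. edgeR recovered 1.2%, 27.6%, 66% and 85.6%, with 6.04% false calls. Camera found the changed list, with every member raised 4-fold, in 5 of 5 data sets and the unchanged list in 0 of 5. Genes were simulated independently of each other, so this trial could not test camera on lists of correlated genes.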

Results

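RNA was sequenced from animal caps of Xenopus laevis, pieces of embryonic ectoderm that become epidermis when cultured on their own. Embryos were injected at the 2-cell stage and caps were dissected at about stage 10. There were 5 groups of 2 libraries each. Wild-type caps had no treatment. In the other groups, noggin RNA, which encodes an inhibitor of BMP signalling that turns ectoderm neural, was combined with retinoic acid, which gives neural tissue a posterior character. That pair of treatments was given alone or with RNA for prdm12, for prdm12 fused to the VP16 activation domain, or for prdm12 fused to the engrailed repressor domain (engR). Prdm12 is a zinc-finger transcription factor of the p1 progenitor domain of the spinal cord and hindbrain, which gives rise to inhibitory V1 interneurons marked by en1. FLAG-tagged prdm12 was also immunoprecipitated from caps with and without noggin and retinoic acid, with 1 ChIP library and 1 input library for each condition.

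Each RNA library held between 11986697 and 15893668 reads on genes, and between 14599 and 15053 genes had a read. The 10 most abundant genes took 16.9% and 15.8% of these reads in the wild-type libraries and between 8.15% and 9.54% in the others. Levels below are normalized read counts, given as mean ± SD with n = 2 libraries per group. Fold changes are on the log2(value + 1) scale ± SE, which understates the change of low genes.

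The prdm12 gene itself had 5.18 ± 5.78 normalized reads in wild-type caps, 53.5 ± 34.3 with noggin and retinoic acid, 184 ± 34.8 with prdm12, 211 ± 72.1 with prdm12-engR and 315 ± 90.8 with prdm12-VP16. It rose with noggin and retinoic acid (log2 fold change 3.40 ± 0.77, adjusted p = 0.00746, limma). Its differences between the construct groups and noggin with retinoic acid did not pass the test (adjusted p = 0.699 for prdm12, 0.2298 for engR and 0.5297 for VP16). The counts do not separate injected RNA from transcripts of the embryo's own gene, and the labels do not give the species of the injected coding sequence. The labels of engR replicate 1 name 2 constructs, engR in the title and VP16 in the treatment. Levels of en1 in that library were 268 normalized reads, against 264 in engR replicate 2 and 1.15 and 1.96 in the VP16 libraries.

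The first comparison asked what noggin and retinoic acid did to ectoderm. Most members of the posterior neural lists rose and most epidermal list members fell. The retinoic acid-degrading enzyme cyp26a1 rose from 365 ± 11.2 to 109490 ± 6513 normalized reads (log2 fold change 8.22 ± 0.23, adjusted p = 1.3e-06). Another enzyme of that family, cyp26c1, rose from 82.01 ± 18.7 to 27871 ± 9887. The hindbrain and spinal cord patterning gene hoxb4 rose from 16.8 ± 0.559 to 5279 ± 1347, and hoxc4 rose from 60.1 ± 12.3 to 7369.9 ± 348. The epidermal keratin krt12 fell from 262901 ± 28954 to 177 ± 44.96 (log2 fold change -10.55 ± 0.35, adjusted p = 1.3e-06). The secreted lectin ITLN2 fell from 188059 ± 24975 to 101 ± 85.4, and FCGBP, a mucus protein gene, fell from 41480.5 ± 13254 to 24.9 ± 11.003.

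Of 42 measured genes of the hindbrain, spinal cord and retinoic acid list, 35 rose and 2 fell, and the counts were the same adjusted over the list alone (camera adjusted p = 9.5e-16, adjusted p = 0.0658 with an estimated correlation). Of 21 pan-neural progenitor genes, 16 rose and 1 fell, also adjusted over the list alone (median log2 fold change 4.32, adjusted p = 0.0842 with an estimated correlation). The RNA-binding protein gene msi1 rose from 44.2 ± 2.55 to 8602 ± 707 and nes, an intermediate filament gene of neural stem cells, from 12.5 ± 0.863 to 2038 ± 85.4. The progenitor gene sox3 rose from 21.6 ± 1.21 to 2506 ± 443, and the eye and neural tube regulator pax6 from 17.1 ± 5.69 to 3200.1 ± 640.4. Of 27 neuronal differentiation genes, 25 rose and none fell, and 26 rose adjusted over the list alone (adjusted p = 0.107 with an estimated correlation). They included the proneural factor neurod4 (6.82 ± 3.45 to 1924 ± 52.8), ebf2 (10.5 ± 3.67 to 1422 ± 55.5) and dcx, a microtubule protein gene of migrating neurons (6.04 ± 0.813 to 323 ± 31.4).

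Of 23 genes of the domains that flank the V1 lineage, 15 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.0955 with an estimated correlation). The p0 domain gene dbx1 rose from 2.53 ± 2.04 to 874 ± 211 normalized reads and the V2 progenitor gene vsx1 from 4.72 ± 1.06 to 1566 ± 299. The ventral progenitor gene nkx6-1 had 872 recovered reads against 2 in wild-type caps, a ratio of 300.1 with a 95% counting interval of 82.8 to 2482, and nkx6-2 rose from 8.69 ± 4.55 to 777 ± 120.2. Of 14 V1 list genes, which include prdm12, 9 rose and none fell, also adjusted over the list alone (adjusted p = 0.107 with an estimated correlation). The interneuron regulator lhx1 rose from 16.2 ± 7.98 to 2059 ± 1148 and foxp2 from 40.9 ± 42.8 to 501 ± 0.382. Levels of en1 were near the detection limit (0.66 ± 0.933 and 3.27 ± 2.27, adjusted p = 0.105). Of 12 dorsal neural genes, 6 rose and 2 fell, or 9 and 2 adjusted over the list alone. The neural tube gene pax3 rose from 31.9 ± 1.73 to 709 ± 22.5, and msx2 fell (log2 fold change -9.38 ± 0.67). That list did not pass camera (adjusted p = 0.0708). Of 7 anterior neural genes, 2 rose and 3 fell, or 4 and 3 adjusted over the list alone. The forebrain and eye gene six3 rose, with 167 recovered reads against 3 (ratio 38.3, 95% counting interval 12.9 to 188). Those that fell included the forebrain genes otx2 (722 ± 662 to 10.3 ± 1.96) and emx2 (212 ± 4.74 to 6.64 ± 4.801). The median of that list (2.04) differed in sign from its mean (-0.13) and its test (camera adjusted p = 0.921).

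Of 26 epidermal genes, 25 fell and 1 rose, with the same counts adjusted over the list alone (median log2 fold change -5.20, camera adjusted p = 3.5e-11, adjusted p = 0.0658 with an estimated correlation). The cornified envelope gene ppl fell from 16507 ± 2159 to 332 ± 161 and the protease gene capn9 from 19149.6 ± 4763 to 9.18 ± 10.7. Of 18 genes of goblet cells, ionocytes and small secretory cells, 15 fell and 1 rose, also adjusted over the list alone, and this list kept its camera call with an estimated correlation (adjusted p = 0.0347). They included the anion exchanger slc26a4 (15007 ± 8860.3 to 11.1 ± 1.53) and agr2, needed for mucin folding (3733 ± 72.7 to 8.69 ± 3.097), and the ionocyte and placode regulator foxi1 fell from 3764 ± 1286 to 4.1 ± 2.25. Of 16 BMP response genes, 11 fell and 2 rose, or 13 and 2 adjusted over the list alone (adjusted p = 0.195 with an estimated correlation). The BMP target genes bambi and szl fell from 5788 ± 2270.2 to 23.97 ± 5.15 and from 981 ± 524 to 11.5 ± 0.233. Multiciliated cell genes went both ways, with 4 up and 8 down of 26, also adjusted over the list alone (camera adjusted p = 0.1197). The tektin tekt3 fell from 2927 ± 1725 to 52.3 ± 6.53 and myb from 519 ± 143 to 6.17 ± 1.63.

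Of 17 Notch pathway genes, 11 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.107 with an estimated correlation). Among those that rose were the Notch modifier lfng (161 ± 5.55 to 5359 ± 267) and the ligand dlc (11.7 ± 4.11 to 957 ± 238). Of 23 mesodermal genes, 11 rose and 4 fell, or 12 and 4 adjusted over the list alone (adjusted p = 0.329 with an estimated correlation). Genes that rose included the kidney and mesoderm gene osr1, with 1319 recovered reads against 1 in wild-type caps (ratio 908, 95% counting interval 162.7 to 35890), and the muscle regulator myod1, with 609 against 1 (ratio 419, 74.96 to 16585). The heart genes hand2 (1693 ± 321 to 11.9 ± 1.51) and nkx2-5 (969 ± 403 to 2.07 ± 0.622) were among those that fell. Of 14 endodermal genes, 9 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.287 with an estimated correlation). Genes that rose included the protease inhibitor a2m (238 ± 102 to 2157 ± 445). Of 25 neural crest genes, 10 rose and 6 fell, or 10 and 7 adjusted over the list alone, with sox9 up from 50.02 ± 13.5 to 1119 ± 9.16 and tfap2c down from 4009.8 ± 567 to 29.1 ± 13.99. The list median (-0.60) differed in sign from its mean (0.11) and its test. Of 23 placode and sensory neuron genes, 8 rose and 8 fell, or 9 and 8 adjusted over the list alone, among those that fell the ion channel trpa1 (1597 ± 1032 to 4.96 ± 1.27). Of 20 Wnt and FGF genes, 7 rose and 6 fell, or 8 and 7 adjusted over the list alone. The ligand wnt11 rose from 9.21 ± 5.54 to 2857 ± 315, the FGF feedback gene spry2 rose from 306 ± 145 to 2123 ± 645 and the phosphatase dusp6 fell from 1606 ± 508 to 304 ± 61.5. The stress list had 3 up and 4 down of 25, or 3 and 3 adjusted over the list alone. The transcription factor jun rose from 1023 ± 707 to 6746 ± 1673 and the chaperone hspa5 fell from 58856 ± 12072 to 20229.9 ± 375. Of 28 cell cycle genes 3 rose, including the mitotic phosphatase cdc25b (82.9 ± 14.3 to 508 ± 38.7), and the list median (-0.13) and mean (-0.02) were below 0 while its test was directed upwards. Of 19 housekeeping genes 1 rose and 3 fell, including actb (138792 ± 26781 to 46639 ± 2303), with a list median of -0.32 that became 0.06 after quantile normalization. For both lists the counts were the same adjusted over the list alone. Camera did not call the neural crest, placode, Wnt and FGF, stress, cell cycle and housekeeping lists (adjusted p = 0.795, 0.8405, 0.737, 0.698, 0.968 and 0.457).

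In all, 5655 of 12937 genes passed the limma test at an adjusted p under 0.05 (Benjamini-Hochberg), 2887 higher and 2768 lower. Over all genes, fold changes within replicate number 1 and within replicate number 2 correlated at r = 0.92 here and at 0.44 to 0.80 in the other 6 comparisons. Of the 20 gene lists, 11 passed camera and 1 passed with an estimated correlation.

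The next comparison asked what prdm12 added to noggin and retinoic acid. Of the V1 list 3 genes rose, and 2 genes of neighbouring progenitor domains fell. The V1 marker en1 (ENSXETG00000014994, positions 3638 to 9595 of scaffold GL176628.1 in the deposited table) rose from 3.27 ± 2.27 to 391 ± 129.5 normalized reads (log2 fold change 6.59 ± 0.61, adjusted p = 0.0197). The ratio of recovered reads was 117, with a 95% counting interval of 59.1 to 272. The vesicular transporter of GABA and glycine slc32a1 rose from 58.1 ± 33.8 to 3916 ± 1053 (6.15 ± 0.58, adjusted p = 0.0197) and the interneuron regulator pax2 from 59.2 ± 23.9 to 1434 ± 84.7 (4.63 ± 0.50). The ventral progenitor gene nkx6-1 fell from 359 ± 95.4 to 18.95 ± 5.904 (-4.18 ± 0.48, adjusted p = 0.0197) and the V2 gene vsx1 from 1566 ± 299 to 309.5 ± 35.4 (-2.33 ± 0.26). The plot of read counts in each library shows these genes.

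**Figure D1:**
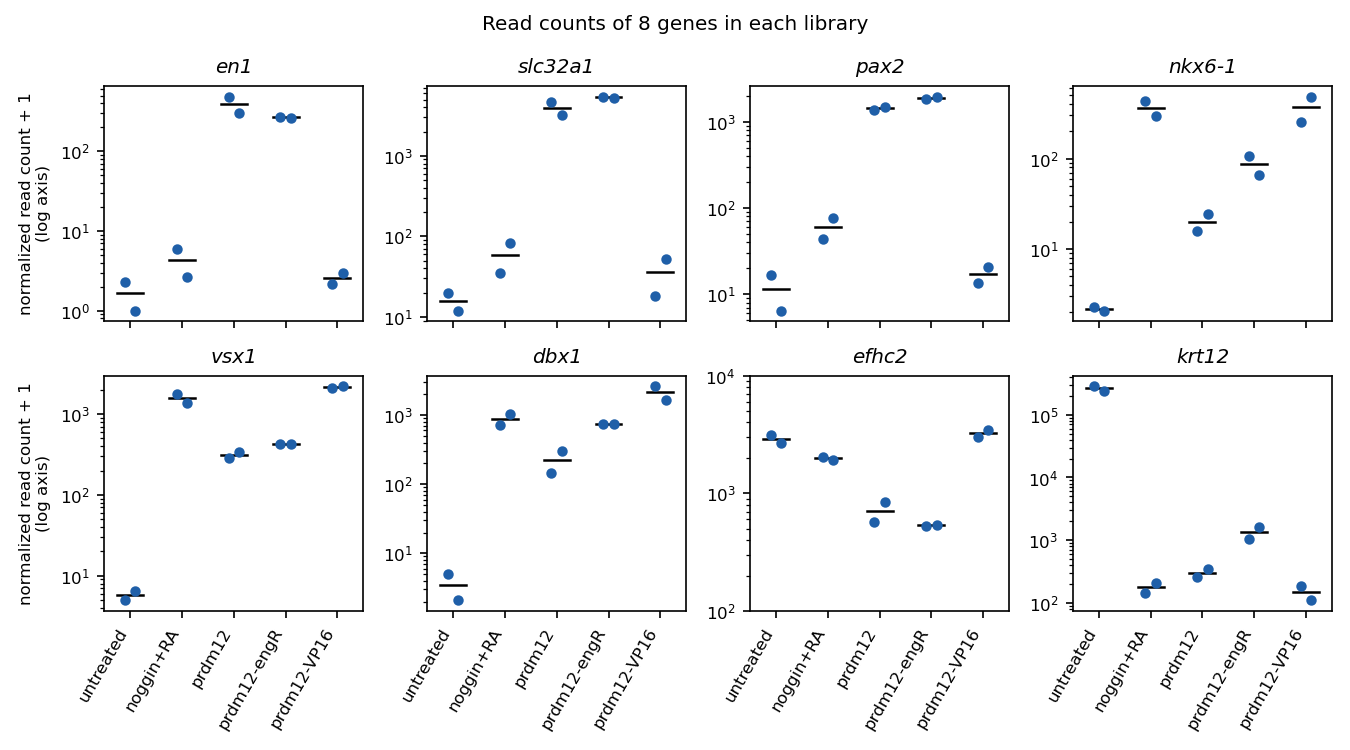
Normalized read count + 1 (log axes) of 8 genes in each of the 10 libraries, with points for libraries and lines for group means. The level of en1 was 482 and 299 in the prdm12 libraries, 268 and 264 in the engR libraries and 4.88 or less in each of the others.

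Of 14 V1 list genes, 3 rose over all genes and 8 adjusted over the list alone, and none fell (camera adjusted p = 2.0e-15, adjusted p = 0.0265 with an estimated correlation, the only list to pass that test here). Of the list members outside the 3, foxd3, a factor of neural crest and V1 neurons, had 32.8 ± 20.3 and 1111 ± 148 normalized reads (adjusted p = 0.115). Other genes that rose were the RNA editing family gene adarb2 (20.2 ± 4.84 to 716 ± 45.8) and the potassium channel genes kcnk12 (4.12 ± 1.08 to 185 ± 56.6) and kcng2 (9.07 ± 0.184 to 183 ± 14.5). So did the motor and sensory neuron gene isl2 (43.8 ± 12.5 to 576 ± 22.7) and the endoplasmic reticulum protein gene erp29 (22.3 ± 5.11 to 271 ± 42.1). Of 23 flanking domain genes, 1 rose and 2 fell over all genes, and 5 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.0484, adjusted p = 0.333 with an estimated correlation). Levels of dbx1 were 874 ± 211 with noggin and retinoic acid and 224 ± 112 with prdm12 (adjusted p = 0.307). Those of nkx6-2 were 777 ± 120.2 and 974 ± 656 (adjusted p = 1).

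None of 26 multiciliated cell genes passed over all genes, and 9 fell adjusted over the list alone (camera adjusted p = 6.1e-15, adjusted p = 0.142 with an estimated correlation). Levels of efhc2 were 1986 ± 71.3 and 703 ± 195 (adjusted p = 0.0606), and those of the tektin tekt2 1697 ± 328 and 566 ± 42.8. For foxj1, the master regulator of motile cilia, they were 1633 ± 407 and 710.2 ± 15.4. Of 21 pan-neural genes 6 were higher and 1 fell adjusted over the list alone (adjusted p = 0.142 with an estimated correlation). Levels were 2506 ± 443 and 927 ± 405 for sox3 and, for msi1, 8602 ± 707 and 4957 ± 1278. Of 14 endodermal genes 12 were higher and 5 rose adjusted over the list alone (adjusted p = 0.142 with an estimated correlation). For a2m the levels were 2157 ± 445 and 6369.9 ± 1133, and for foxa2, which is also a floor plate gene, 58.4 ± 10.5 and 186 ± 34.6. Of 26 epidermal genes 22 were higher and 1 rose adjusted over the list alone (adjusted p = 0.235 with an estimated correlation), with gata3 at 74.4 ± 27.1 and 378 ± 144. The sensory neuron and dorsal horn gene tlx3 had 8.65 ± 0.403 and 108 ± 21.7 normalized reads (adjusted p = 0.0906).

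The limma test called 21 of 12937 genes, 19 higher and 2 lower, and 828 genes had an unadjusted p under 0.05. Camera passed 9 of the 20 lists. With the replicate number as a block limma called 121 genes, 102 higher and 19 lower, the 21 among them. The blocked test also called foxd3 (adjusted p = 0.0246), tlx3 and efhc2 (both 0.0262) and tekt2 (0.0444). The flanking domain, placode and Notch lists lost their camera calls with the block (adjusted p = 0.0608, 0.0982 and 0.0698). DESeq2 called 253 genes, and a model of these 2 groups alone called 0. Without noggin replicate 1 the count was 1, and without noggin replicate 2 or any 1 of the prdm12 or engR libraries it was 0. Without VP16 replicate 1 or 2 it was 33 or 32, and without wild-type replicate 1 or 2 it was 8 or 10.

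With the engR fusion, which adds a repressor domain to prdm12, members of the V1, placode and sensory neuron and epidermal lists rose, and members of the multiciliated cell list fell. Levels of en1 rose from 3.27 ± 2.27 with noggin and retinoic acid to 266 ± 2.98 (6.07 ± 0.61, adjusted p = 0.00485). The transporter slc32a1 rose from 58.1 ± 33.8 to 5351 ± 94.5 (6.63 ± 0.58) and pax2 from 59.2 ± 23.9 to 1884 ± 84.4 (5.03 ± 0.50, adjusted p = 0.00485). The neuropeptide gene sst rose from 9.88 ± 0.969 to 3401 ± 1945 (8.16 ± 0.76, adjusted p = 0.00379), and the homeobox gene hmx3 from 21.5 ± 6.26 to 1951 ± 246. The mechanically gated channel PIEZO2 rose from 37.5 ± 2.16 to 679.9 ± 134 and the epidermal keratin krt12 from 177 ± 44.96 to 1339 ± 431, against 262901 ± 28954 in wild-type caps. The ciliary gene efhc2 fell from 1986 ± 71.3 to 534 ± 4.999 (-1.89 ± 0.23, adjusted p = 0.008904).

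Of 14 V1 list genes, 5 rose and none fell, with 9 up adjusted over the list alone (camera adjusted p = 1.4e-08, adjusted p = 0.05295 with an estimated correlation). They included pax8 (42.7 ± 20.1 to 378 ± 50.1) and foxd3 (32.8 ± 20.3 to 861 ± 203), and adarb2, outside the list, rose from 20.2 ± 4.84 to 1063 ± 36.4. Of 23 flanking domain genes, 4 rose and 1 fell, or 5 and 5 adjusted over the list alone. The test of that list (camera adjusted p = 0.813) was directed downwards while its median was 0.01 (-0.04 after quantile normalization) and its mean 0.33. Those that rose included foxa2 (58.4 ± 10.5 to 928 ± 244), gata3, a gene of V2b neurons and of epidermis (74.4 ± 27.1 to 1349 ± 356), and isl2 (43.8 ± 12.5 to 476 ± 21.6). The V2 gene vsx1 fell from 1566 ± 299 to 428 ± 3.698. Levels of nkx6-1 were 359 ± 95.4 and 85.1 ± 28.6 (adjusted p = 0.0593), those of dbx1 874 ± 211 and 741 ± 13.5 (0.91) and those of nkx6-2 777 ± 120.2 and 780.4 ± 90.9. Of 23 placode and sensory neuron genes, 4 rose and 1 fell, or 8 and 2 adjusted over the list alone (adjusted p = 0.05295 with an estimated correlation). Besides PIEZO2, the nociceptor homeobox gene DRGX rose from 7.85 ± 1.91 to 129.6 ± 4.03 and the cyclooxygenase ptgs1 from 20.1 ± 7.17 to 463 ± 119.9. A gene of autonomic and cranial neurons, phox2a, fell from 42.5 ± 7.27 to 4.68 ± 5.17. The neuron gene tlx3, also on the dorsal list, rose from 8.65 ± 0.403 to 213 ± 12.1.

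Of 26 epidermal genes, 6 rose and none fell, with 12 up adjusted over the list alone (median 2.44, camera adjusted p = 1.4e-08, adjusted p = 0.0982 with an estimated correlation). They included the epithelial regulators grhl2 (15.3 ± 9.06 to 162 ± 33.6) and tfap2c (29.1 ± 13.99 to 380.1 ± 170.3). Of 14 endodermal genes 4 rose, or 7 adjusted over the list alone, and none fell (adjusted p = 0.141 with an estimated correlation). The protease inhibitor a2m rose from 2157 ± 445 to 15549.8 ± 3799.8 and the intestinal and tail bud gene cdx2 from 4.495 ± 3.995 to 46.1 ± 1.81. Of 20 Wnt and FGF genes 3 rose, or 8 with 1 down adjusted over the list alone (adjusted p = 0.225 with an estimated correlation). All 3 are FGF feedback or target genes, spry1 (9.91 ± 1.37 to 64.8 ± 7.15), etv1 (1200.3 ± 451 to 3977 ± 909) and dusp6 (304 ± 61.5 to 979.7 ± 40.6). The BMP target id4 (893 ± 49.5 to 2335 ± 450) and the immediate early gene egr1 (310.2 ± 30.5 to 966 ± 185) also rose. Of 26 multiciliated cell genes 10 fell, or 17 with 1 up adjusted over the list alone (camera adjusted p = 2.5e-14, adjusted p = 0.104 with an estimated correlation). The tektins tekt1 (1176 ± 327 to 265 ± 1.42) and tekt2 (1697 ± 328 to 335 ± 50.7) and the dynein heavy chain DNAH9 (593 ± 44.03 to 103 ± 1.61) were among them. Of 21 pan-neural genes 3 fell, or 8 adjusted over the list alone (adjusted p = 0.141 with an estimated correlation). They included msi1, from 8602 ± 707 to 3168 ± 24.7, and sox3, from 2506 ± 443 to 647 ± 101. Further genes that fell were the neuropeptide gene vip (291 ± 74.6 to 31.1 ± 8.53), the adhesion receptor gene GPR144 (11027 ± 254 to 1916 ± 872) and the sarcomeric actin gene actc1 (2233 ± 873 to 386 ± 63.4).

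The limma test called 444 genes, 312 higher and 132 lower. After quantile normalization 507 were called, 55.4% of them higher against 70.3% before, and DESeq2 called 1167. With the replicate block limma called 1414, among them nkx6-1 (adjusted p = 0.0271), and the Wnt and FGF list lost its camera call (adjusted p = 0.0527). The share of read records not aligned uniquely was 34.2% ± 0.0978 in engR libraries against 27.1% ± 0.895 with noggin and retinoic acid. Without engR replicate 1, the library with the conflicting label, or engR replicate 2 the count was 4, and without noggin replicate 1 or 2 it was 52 or 46.

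The VP16 fusion, which adds an activation domain to prdm12, had no gene past the test against noggin and retinoic acid in the model without a replicate block, and 44 with it. The limma count was 0 of 12937 genes, with 868 at an unadjusted p under 0.05, 0 by edgeR on recovered reads and 130 by DESeq2. With the block, limma called 14 genes higher and 30 lower and edgeR called 42. The blocked test called foxa1 (adjusted p = 0.0226), nes and krt8 (both 0.0378), and the anterior neural list lost its camera call (adjusted p = 0.0964). The pioneer factor gene foxa1 had the smallest adjusted p among the genes named here (0.0725), with 2141 ± 446 normalized reads with noggin and retinoic acid and 467 ± 23.2 with VP16. Levels were 59.2 ± 23.9 and 16.1 ± 4.94 for pax2, 2059 ± 1148 and 544 ± 331 for lhx1, 532 ± 329.7 and 86.9 ± 85.4 for the glycine transporter slc6a5 and 3.27 ± 2.27 and 1.55 ± 0.573 for en1. They were 2038 ± 85.4 and 4925 ± 883 for nes, 10572 ± 2257 and 27254 ± 5897 for the simple epithelial keratin krt8 and 42.5 ± 7.27 and 422 ± 32.4 for phox2a. The axonal genes nefm (12697 ± 4598 and 2638 ± 2254), gap43 (2865 ± 449 and 772 ± 722) and stmn2 (2222 ± 623 and 683 ± 691) varied widely between the VP16 libraries. For dbx1 the levels were 874 ± 211 and 2127 ± 672 (adjusted p = 0.693). They were for nkx6-1 359 ± 95.4 and 365 ± 164, for nkx6-2 777 ± 120.2 and 903 ± 58.1 and for actc1 2233 ± 873 and 359 ± 57.9. Of 14 V1 list genes 13 were lower and 4 fell adjusted over the list alone, with 1 up (camera adjusted p = 0.00106, adjusted p = 0.513 with an estimated correlation). The 1 that was up was prdm12 itself, whose counts do not separate injected RNA from the embryo's own transcripts. Of 28 cell cycle genes 25 were higher (camera adjusted p = 0.00125, adjusted p = 0.573 with an estimated correlation), with the replication gene pcna at 1119 ± 464 and 2339.8 ± 1014. Without VP16 replicate 2 the count was 197, 16 higher and 181 lower, without engR replicate 1 or 2 it was 1, and after quantile normalization it was 2.

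Set against prdm12 itself, VP16 caps had lower levels of 8 genes of the V1 list and higher levels of nkx6-1, dbx1 and vsx1 of the flanking domains. The GABA-synthesizing enzyme gad1 fell from 4210.1 ± 258 with prdm12 to 18.3 ± 22.7 with VP16 (-8.61 ± 1.14, adjusted p = 0.00942). The transporter slc32a1 fell from 3916 ± 1053 to 34.6 ± 24.6 (-6.95 ± 0.58) and pax2 from 1434 ± 84.7 to 16.1 ± 4.94 (-6.42 ± 0.50). For en1 the prdm12 libraries had 884 recovered reads and the VP16 libraries 3, a ratio of 242 with a 95% counting interval of 82.7 to 1178. The flanking genes nkx6-1 and dbx1 rose from 18.95 ± 5.904 to 365 ± 164 (4.16 ± 0.48, adjusted p = 0.00511) and from 224 ± 112 to 2127 ± 672 (3.30 ± 0.51, adjusted p = 0.0155). The V2 gene vsx1 rose from 309.5 ± 35.4 to 2143 ± 84.3. The BMP antagonist grem1 rose from 17.2 ± 16.2 to 1482 ± 541 and the ligand bmp7.1 from 18.98 ± 5.81 to 708 ± 417.

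Of 14 V1 list genes 8 fell, or 10 adjusted over the list alone, and none rose (camera adjusted p = 7.2e-10, adjusted p = 0.0725 with an estimated correlation). The factor foxd3 fell from 1111 ± 148 to 8.88 ± 6.99. Of 23 flanking domain genes 3 rose and 4 fell, or 8 and 6 adjusted over the list alone (camera adjusted p = 0.0679). Those that fell included isl2 (576 ± 22.7 to 39.8 ± 17.3) and gata3 (378 ± 144 to 24.95 ± 10.3). Of 26 multiciliated cell genes 5 rose, or 13 adjusted over the list alone (adjusted p = 0.23002 with an estimated correlation). They included efhc2 (703 ± 195 to 3245 ± 319) and tekt2 (566 ± 42.8 to 2359 ± 109). Of 21 pan-neural genes 4 rose, or 8 adjusted over the list alone (adjusted p = 0.23002 with an estimated correlation). They included nes (1272 ± 97.5 to 4925 ± 883) and zic2 (14.4 ± 0.714 to 117 ± 56.6). The Notch ligand dlc rose from 466 ± 123 to 1525 ± 230.3. Of 14 endodermal genes 5 fell, or 8 adjusted over the list alone (adjusted p = 0.23002 with an estimated correlation). They included a2m (6369.9 ± 1133 to 1298 ± 376) and foxa1 (2480.5 ± 484 to 467 ± 23.2). Of 27 neuronal differentiation genes 4 fell, or 9 with 1 up adjusted over the list alone (adjusted p = 0.559 with an estimated correlation). They included nefm (19548 ± 3567 to 2638 ± 2254) and gap43 (5296 ± 811 to 772 ± 722). Of 23 placode and sensory neuron genes 5 fell and 1 rose, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0806). The neurotrophic factor receptor gfra3 fell from 426 ± 100.2 to 54.1 ± 17.9 and phox2a rose from 10.8 ± 3.47 to 422 ± 32.4. Further genes that fell were adarb2 (716 ± 45.8 to 9.11 ± 1.77), the kinase-like gene camkv (3423 ± 734 to 65.5 ± 60.1) and tlx3 (108 ± 21.7 to 10.7 ± 7.04). Levels of nkx6-2 were 974 ± 656 and 903 ± 58.1 (adjusted p = 0.961).

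The limma test called 500 genes, 98 higher and 402 lower in VP16. With the replicate block it called 2125, 625 higher and 1500 lower, and the anterior neural, epidermal and Notch lists lost their camera calls (adjusted p = 0.0651, 0.0541 and 0.0708). DESeq2 called 1304 and a model of these 2 groups alone 0. The count was 326 or 314 without noggin replicate 1 or 2 and 142 or 857 without VP16 replicate 1 or 2. It was 175 or 180 without engR replicate 1 or 2 and 58 or 93 without prdm12 replicate 1 or 2.

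Between VP16 and engR, the fusions with an activator and with a repressor domain, members of the V1, placode and sensory neuron, epidermal and endodermal lists were lower in VP16 and members of the multiciliated cell and pan-neural lists were higher. Levels of sst fell from 3401 ± 1945 with engR to 5.91 ± 1.41 with VP16 (-8.83 ± 0.76, adjusted p = 9.0e-04) and gad1 from 2165 ± 55.7 to 18.3 ± 22.7 (-7.65 ± 1.14). The transporter slc32a1 fell from 5351 ± 94.5 to 34.6 ± 24.6 (-7.43 ± 0.58) and the glutamate receptor gene grin2a from 878 ± 513 to 5.49 ± 6.13. For en1 the engR libraries had 513 recovered reads against 3, a ratio of 167 with a 95% counting interval of 56.9 to 814. Levels of phox2a rose from 4.68 ± 5.17 to 422 ± 32.4 (6.60 ± 0.72, adjusted p = 0.00224) and grem1 from 23.3 ± 3.86 to 1482 ± 541. The fatty acid amide hydrolase family gene faah.3 rose from 11.3 ± 13.1 to 638 ± 77.7 and the fatty acid elongase elovl2 from 20.7 ± 14.5 to 796 ± 109. The progenitor gene nkx6-1 rose from 85.1 ± 28.6 to 365 ± 164 (adjusted p = 0.0299). The difference for dbx1 did not pass (741 ± 13.5 and 2127 ± 672, 0.101), nor that for nkx6-2 (780.4 ± 90.9 and 903 ± 58.1, 0.828).

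Of 14 V1 list genes 10 fell, also adjusted over the list alone, and none rose (adjusted p = 0.0744 with an estimated correlation). They included pax2 (1884 ± 84.4 to 16.1 ± 4.94) and foxd3 (861 ± 203 to 8.88 ± 6.99). Of 26 multiciliated cell genes 14 rose, or 18 with 1 down adjusted over the list alone (adjusted p = 0.142 with an estimated correlation). The ciliary gene efhc2 rose from 534 ± 4.999 to 3245 ± 319 and tekt2 from 335 ± 50.7 to 2359 ± 109. Of 21 pan-neural genes 9 rose, or 11 with 1 down adjusted over the list alone (adjusted p = 0.142 with an estimated correlation). They included nes (1294 ± 131 to 4925 ± 883) and msi1 (3168 ± 24.7 to 10568 ± 1115). Of 26 epidermal genes 12 fell and 1 rose, or 17 and 3 adjusted over the list alone (adjusted p = 0.142 with an estimated correlation). Among those that fell were grhl2 (162 ± 33.6 to 4.09 ± 2.54) and gata3 (1349 ± 356 to 24.95 ± 10.3). Of 14 endodermal genes 9 fell, or 11 adjusted over the list alone (adjusted p = 0.142 with an estimated correlation). They included a2m (15549.8 ± 3799.8 to 1298 ± 376) and foxa1 (1941 ± 126 to 467 ± 23.2). Of 23 placode and sensory neuron genes 9 fell and 1 rose, with the same counts adjusted over the list alone (adjusted p = 0.0744 with an estimated correlation). The channel PIEZO2 fell from 679.9 ± 134 to 27.2 ± 2.298, and tlx3, also on the dorsal list, fell from 213 ± 12.1 to 10.7 ± 7.04. Of 27 neuronal differentiation genes 7 fell, or 9 with 2 up adjusted over the list alone (camera adjusted p = 0.0815). Among them were nefm (17951 ± 2555 to 2638 ± 2254) and stmn2 (7685 ± 1127 to 683 ± 691).

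The limma test called 1567 genes, 442 higher and 1125 lower in VP16. After quantile normalization 45.04% of the calls were higher, against 28.2% before. With the replicate block limma called 3770 genes, and the housekeeping list passed camera (adjusted p = 0.0386). DESeq2 called 2427 and a model of these 2 groups alone 640, and the count was 731 without VP16 replicate 1, 474 without engR replicate 1 and 325 without engR replicate 2.

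Between engR and prdm12 no gene passed the limma test (679 had an unadjusted p under 0.05, edgeR called 0 and DESeq2 177). With the replicate block limma called 13 genes, among them PIEZO2 (adjusted p = 0.0389), and edgeR 40, and the endodermal list lost its camera call (adjusted p = 0.0582). The levels of PIEZO2 were 88.3 ± 27.9 with prdm12 and 679.9 ± 134 with engR (log2 fold change 2.95 ± 0.39, adjusted p = 0.227). Those of DRGX were 9.41 ± 6.29 and 129.6 ± 4.03, those of krt12 302 ± 58.8 and 1339 ± 431 and those of foxa2 186 ± 34.6 and 928 ± 244. For tekt1 they were 551 ± 35.6 and 265 ± 1.42. For the genes named in every comparison they were 18.95 ± 5.904 and 85.1 ± 28.6 (nkx6-1), 224 ± 112 and 741 ± 13.5 (dbx1), 391 ± 129.5 and 266 ± 2.98 (en1) and 974 ± 656 and 780.4 ± 90.9 (nkx6-2). Of 26 epidermal genes 24 were higher with engR and 6 rose adjusted over the list alone (camera adjusted p = 1.8e-10, adjusted p = 0.0882 with an estimated correlation). Of 23 placode and sensory neuron genes 19 were higher and 6 rose adjusted over the list alone (adjusted p = 0.06795 with an estimated correlation). The heat map of list medians sets the 20 lists side by side.

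**Figure D2:**
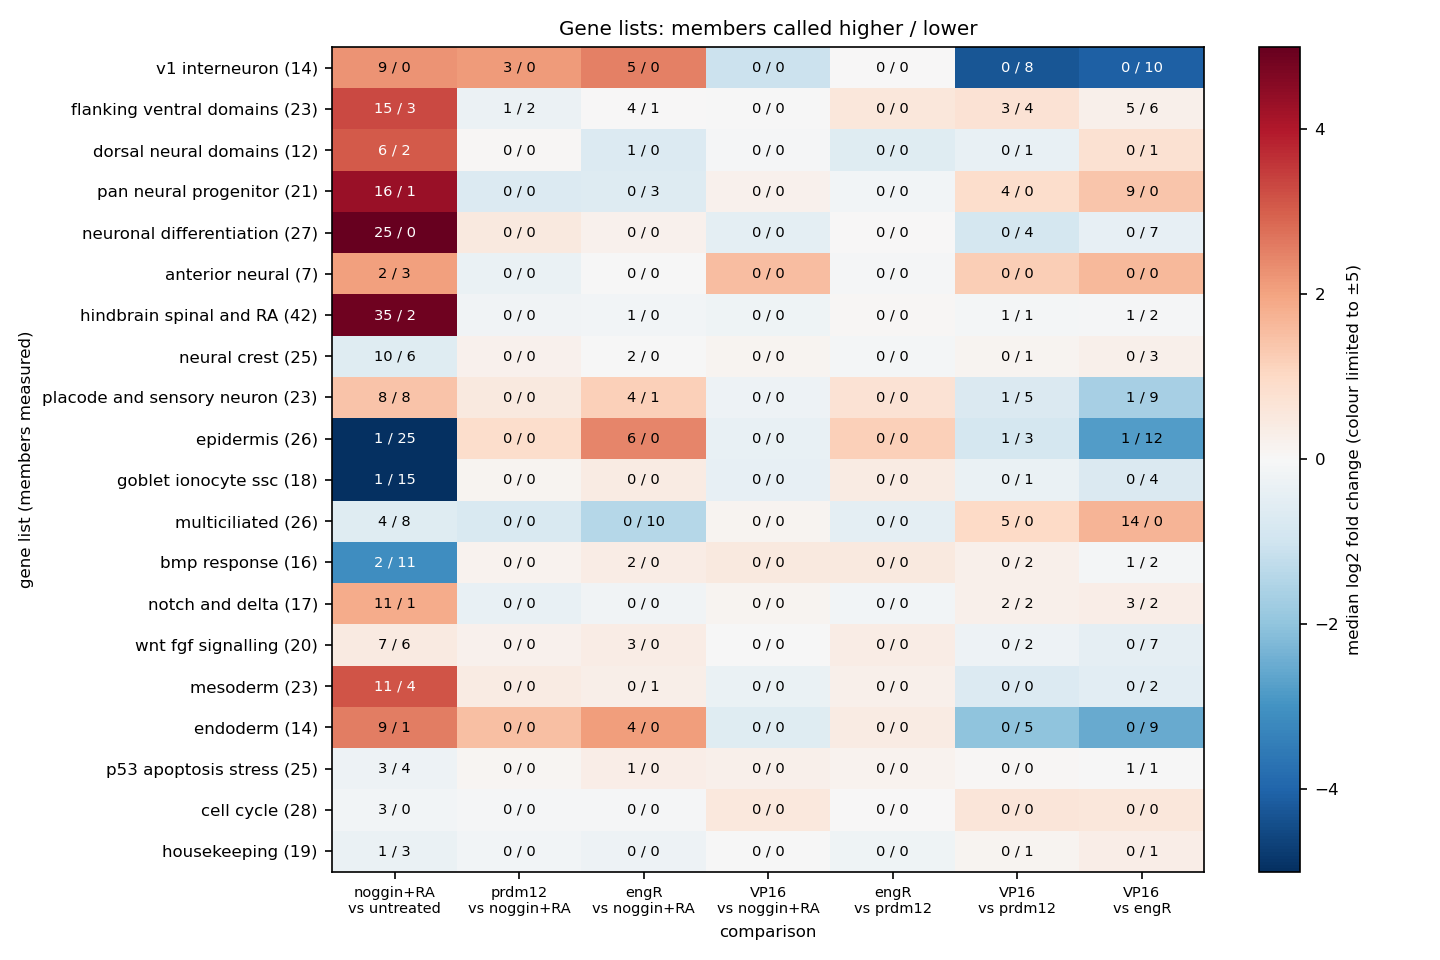
Median log2 fold change (colour) of 20 gene lists in 7 comparisons, with the number of members called higher and lower in each cell. The V1 list has 3 members called higher with prdm12 and 5 with engR against noggin and retinoic acid, and 8 and 10 called lower with VP16 against prdm12 and engR.

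The fold changes of the constructs were then compared over 12937 genes, which are not independent replicates. Against the shared noggin and retinoic acid libraries, prdm12 and engR had r = 0.80 with 79.7% of genes of the same sign, where simulated unchanged groups gave r = 0.50 and 66.7% (100 simulations). Their covariance was 0.557 against a simulated 0.164, a difference of 0.394. For prdm12 and VP16 r was -0.21 and the covariance differed from the simulated one by -0.266, and for engR and VP16 r was -0.24 and the difference -0.337. Both prdm12 and engR called 18 genes higher (0.458 expected of independent lists) and 1 lower (0.0204 expected). All 21 genes called with prdm12, en1, slc32a1, pax2, nkx6-1 and vsx1 among them, had the same sign with engR and 19 were called there. With VP16 against noggin and retinoic acid, 17 of the 21 had the opposite sign and 4 the same sign, and none was called. Part of the excess of calls common to prdm12 and engR may come from the shared control libraries. Shared controls favour the same sign, so they do not account for the opposite signs with VP16. With 1 library left out, the simulated r was 0.67 without a noggin library and 0.41 without a library of either construct, and the replicate numbers were no longer balanced between the groups. For prdm12 and VP16, r was 0.25 without noggin replicate 1, -0.03 without noggin replicate 2, -0.33 without prdm12 replicate 1 and -0.02 without prdm12 replicate 2, and the covariance differed from its simulated value by -0.136, -0.344, -0.357 and -0.174. For engR and VP16, r was 0.12 without noggin replicate 1 and -0.13 without noggin replicate 2, with differences of -0.199 and -0.423. With the replicate block in these models, the difference was -0.241 to -0.181 for prdm12 and VP16, -0.315 to -0.204 for engR and VP16 and 0.425 to 0.515 for prdm12 and engR.

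Pairs of comparisons with no library in common gave r = -0.66 for VP16 against prdm12 and engR against noggin, with 156 genes lower in the first and higher in the latter (9.69 expected) and 34 higher then lower (1.00 expected). For prdm12 against noggin and VP16 against engR r was -0.70, and all 19 genes that rose in the first, such as en1 and slc32a1, fell in the latter (1.65 expected). The scatter plot of construct effects shows the genes called with prdm12 or engR.

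**Figure D3:**
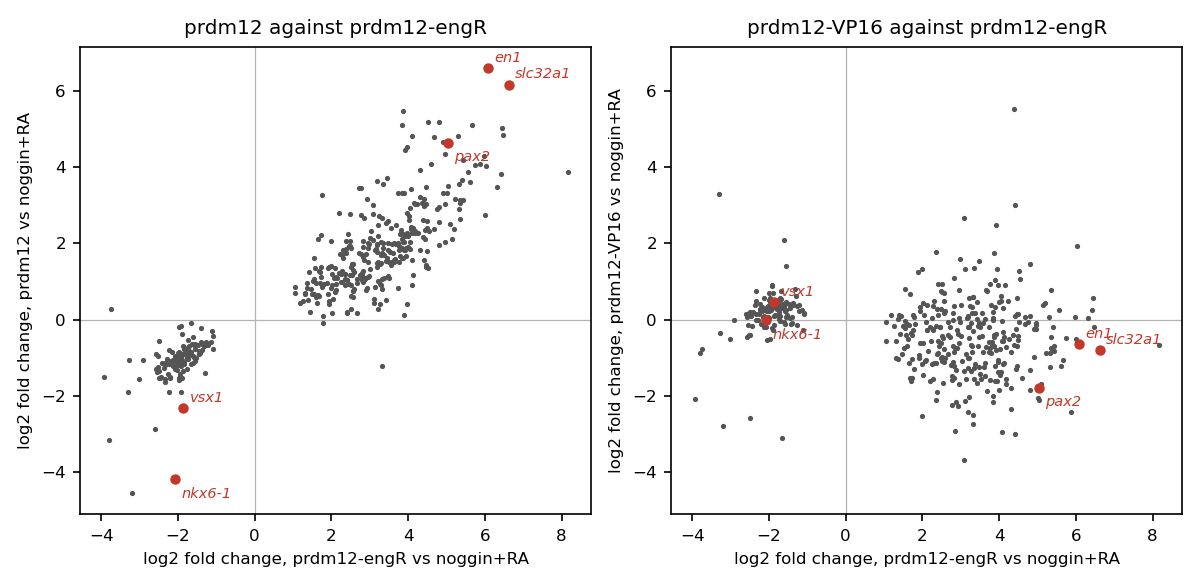
Log2 fold changes against noggin and retinoic acid of the 446 genes called with prdm12 or engR, prdm12 on the left and VP16 on the right, each plotted against engR. The plotted genes were selected by these tests. Over all 12937 genes r was 0.80 between prdm12 and engR and -0.24 between engR and VP16.

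Whether the constructs undid the response to noggin and retinoic acid was tested in the same way, with simulated values of r = -0.50 and covariance -0.163. The simulated noggin and retinoic acid groups had no response of their own against wild type, unlike the data. Simulated r values of the reversal are therefore not what an inactive construct would give, and only the covariances can be compared. The covariance differed from the simulated one by -0.0835 for prdm12 (r = -0.13), -0.347 for VP16 (r = -0.26) and -0.550 for engR (r = -0.26). Of the genes that rose with engR, 200 had fallen with noggin and retinoic acid (66.8 expected), including krt12, tfap2c and grhl2 of the epidermal list, and 53 had risen (69.6 expected). Of those that fell with engR, 39 had risen (29.5 expected) and 31 had fallen (28.2 expected). These expected numbers are for independent lists. The noggin and retinoic acid libraries enter the 2 comparisons with opposite sign, which by itself favours genes that moved in opposite directions, so part of the excess may come from them. The pair with no library in common, noggin and retinoic acid against wild type and VP16 against engR, had r = 0.055 with 52.7% of genes of the same sign. It sets the 2 fusions against each other, so it can only show whether they differed along the response. Whether either fusion undid the response cannot be read from it. In that pair 433 genes rose then fell (251 expected), 437 fell in both (241 expected), 162 rose in both (98.6 expected) and 75 fell then rose (94.6 expected). For prdm12, r was 0.02 without prdm12 replicate 1 and -0.24 without prdm12 replicate 2 (simulated -0.41 for both) and -0.29 without noggin replicate 1 (simulated -0.67), and the covariance differed from its simulated value by 0.213, -0.380 and -0.321. Without noggin replicate 2 the difference was 0.103. For VP16, r was -0.03 without VP16 replicate 1 (simulated -0.41), and the difference was 0.113 without that library, -0.805 without VP16 replicate 2, -0.684 without noggin replicate 1 and -0.0599 without noggin replicate 2. For engR the difference was -0.355 without noggin replicate 2. The sign of the difference for prdm12 and for VP16 therefore depended on single libraries in models without the block. With the replicate block the difference for prdm12 was -0.164, and with 1 library also left out it was -0.253 (without prdm12 replicate 2) to -0.0744 (without prdm12 replicate 1). For VP16 it was then -0.719 to -0.134 (without VP16 replicates 2 and 1) and for engR -0.890 to -0.370 (without engR replicates 1 and 2).

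FLAG-prdm12 ChIP gave 35261 peaks in caps without noggin and retinoic acid and 39464 with them, from 11781620 and 12088205 tags, of which 13.2% and 9.68% lay in peaks. Each list came from 1 ChIP library, with no replicate, and both were called against the same pooled inputs, per the file headers. The peaks had a median and highest width of 167 and 161 bp and lay on 2521 and 2455 scaffolds, and the genome build was not given in the sources used here. The first line of both lists was a peak on Scaffold190753, at positions 311 to 477 and 314 to 474, and no gene annotation of that build was used here. At an overlap of 1 bp or more, 7497 peaks were shared, 21.3% and 19.0% of the lists. Random placement of peaks on their scaffolds gave 343 shared peaks on average (305 to 377 in 100 placements), so that the overlap was 21.8 times the mean. Placement was uniform along each scaffold and did not keep the clustering of peaks given below. The ratio therefore measures only the departure from uniform placement. With each list divided in its deposited order into 10 equal parts, the shared percentage was 36.2% in the first part and 11.3% in the last for the list without noggin and retinoic acid, and 39.9% and 6.94% for the other list. Of neighbouring peaks on a scaffold, 12.2% and 12.1% lay within 2 kb, against 3.82% and 4.23% after random placement.

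**Figure D4:**
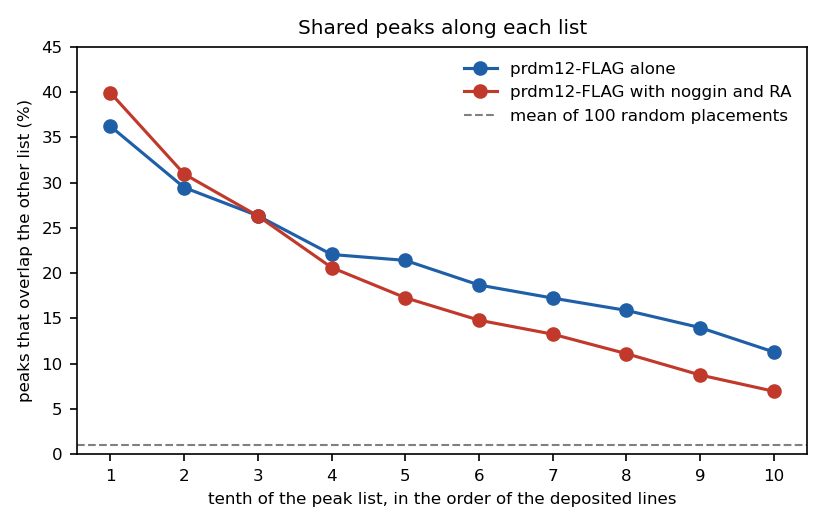
Percent of peaks that overlap a peak of the other list, in each of 10 equal parts of both lists in the order of the deposited lines, with the mean of random placements as a dashed line. Both curves lie above 0.973% in every part, which is the random mean as a percent of the list without noggin and retinoic acid.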

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

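All tests in this part were chosen after the results were seen. The share of read records not aligned uniquely, which no comparison above uses, averaged 34.2% ± 0.0978 in the engR libraries, against 27.1% ± 0.895 with noggin and retinoic acid, 27.7% ± 0.260 with prdm12, 24.8% ± 1.44 with VP16 and 39.2% ± 6.91 in wild-type caps (n = 2 libraries each). The VP16 libraries had as few reads on genes as the engR libraries (12198866 and 12571544 against 12762769 and 11986697) and a mean share of 24.8%. Reads on genes leave out the records not aligned uniquely, so their number is lowered by the share itself. That comparison therefore cannot decide whether low read number was the cause. To reach the engR mean by adding wild-type RNA, 58.6% of the RNA would have to come from cells like those of wild-type caps. That value rests on the mean of 2 wild-type libraries that differed widely (44.0% and 34.3%), and it would change with either one alone. The 20 abundant wild-type transcripts that noggin with retinoic acid brings under 1% of their level imply at most 6.24%, which argues against such cells as the whole cause. An effect of the engR fusion itself remains open and untested.

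Of the epidermal list 6 members were called higher in engR caps, as described above, although most of the list had fallen with noggin and retinoic acid. The list passed camera at a correlation of 0.01 but not with an estimated correlation. Left-over ectoderm could bring such transcripts. The 4 called members that are not keratins would need a median of 29.4% wild-type RNA. By gene the need was 19.9% for grhl2, 38.9% for klf5, 167% for gata3 and 8.75% for tfap2c. The 20 abundant transcripts implied a highest share of 6.24% and a median of 0.470%. No error bounds were set on these shares. They argue against left-over ectoderm as the whole cause for grhl2, klf5 and gata3. They cannot decide for tfap2c, at 380.1 ± 170.3 normalized reads in engR caps. Its spread between libraries was wider than its margin over 6.24%. The 2 called keratins, krt12 and KRT12, need a median of 0.517% (lower 95% bound 0.214%, limma). Of the 20 abundant transcripts, which leave out the called members, 9 imply at least that median. But 4 (ITLN2, slc26a4, ENSXETG00000033322 and XB-GENE-5922677) have an upper bound in engR below the level that even 0.214% would bring. By chance 0.5 would be expected if the noggin levels and the keratin bound were exact. The 20 transcripts share the same libraries and are not independent, so 4 against 0.5 is not a test. ITLN2, for example, would need 503 normalized reads and had 127.6 ± 94.9, with an upper bound of 401. Its level with noggin and retinoic acid, 101 ± 85.4, was taken as exact in that need. These values therefore cannot decide whether ectoderm cells like those of wild-type caps were the whole cause for the keratins. Ectoderm of another make-up and an effect of engR also remain open and untested. Scaling is not the whole cause, since 6 of the 6 called members were also called after quantile normalization.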

How the results depend on the processing

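DESeq2, edgeR with the replicate block, the V1 list without prdm12 and all construct alternatives except genes called in either comparison were chosen after the data were seen. The cause of the changes below was not tested, except that models with fewer libraries have less information on the spread. Counts of called genes for prdm12 against noggin and retinoic acid (21) were 45 with a pseudocount of 4, 38 without an intensity trend, 40 with library weights, 253 by DESeq2, 184 by edgeR with the replicate block and 0 in the 2 groups alone. For VP16 against noggin (0) they were 2 after quantile normalization, 130 by DESeq2 and 42 by edgeR with the block. For engR against noggin (444) they were 781 with library weights, 1167 by DESeq2 and 1588 by edgeR with the block. For VP16 against prdm12 (500) they were 1304, 2108 and, in the 2 groups alone, 0. For engR against prdm12 (0) they were 177 and 40, and for VP16 against engR (1567) 2427, 3864 and 640. In limma with the replicate number as a block the counts were 121, 44, 1414, 2125, 13 and 3770 in the same order, and 7548 against 5655 for noggin and retinoic acid against wild type. The block also ended 9 list calls and added 1 list and 9 named genes, given above, and changed no other call of a named gene or list. Leaving out 1 library gave 4081 to 5687 genes for noggin and retinoic acid against wild type, 0 to 33 for prdm12, 0 to 197 for VP16 and 4 to 478 for engR against noggin, 58 to 857 for VP16 against prdm12, 0 to 0 for engR against prdm12 and 325 to 1662 for VP16 against engR. Lists passing camera with an estimated correlation were 1, 1, 0, 0, 0, 0 and 0 in the 7 comparisons, against 11, 9, 6, 8, 10, 9 and 7. With fry they were 2 for prdm12 and 0 for VP16 against noggin, 5 for VP16 against prdm12 and 1 for engR against prdm12. Without prdm12 in the V1 list no count of lists changed. Among genes called in either comparison, r between prdm12 and engR was 0.90, and r of the engR reversal was -0.33, with no simulated value for genes selected in this way by the comparisons themselves. With 1 library left out, with or without the block, r was 0.63 to 0.84 for prdm12 and engR, -0.33 to 0.25 for prdm12 and VP16, -0.31 to 0.12 for engR and VP16, and for the reversal -0.29 to 0.023 with prdm12, -0.38 to -0.030 with VP16 and -0.36 to -0.17 with engR, where simulated values also change with the library left out. Of 198 named values 148 were called, and 21 alternative values had the other sign, none of them for a called gene. For nkx6-1 in VP16 against noggin (-0.022) they were 0.039 after quantile normalization, 0.015 by edgeR, 0.030 by DESeq2, 0.014 by edgeR with the block and 0.25 and 0.45 without noggin or VP16 replicate 1 (range without 1 library -0.49 to 0.45). For nkx6-2 they were -0.0077 and -0.60 in prdm12 against noggin without noggin or prdm12 replicate 2 (range -0.60 to 0.90). In engR against noggin they were -0.038 after quantile normalization, -0.048 by edgeR, -0.051 with the block and -0.15 and -0.11 without noggin replicate 2 or engR replicate 1 (range -0.15 to 0.17). In VP16 against prdm12 they were -0.062 by edgeR, -0.11 by DESeq2, -0.034 with the block and -0.67 without prdm12 replicate 1 (range -0.67 to 0.82), and in engR against prdm12 0.61 without prdm12 replicate 2 (range -0.89 to 0.61). For dbx1 in engR against noggin the value was 0.032 without noggin replicate 2 (range -0.47 to 0.032), and for prdm12 in engR against prdm12 it was -0.19 and -0.031 without engR or prdm12 replicate 1 (range -0.19 to 0.52). Quantile normalization moved the median of all genes to -0.13 in engR against noggin, 0.14 in VP16 against prdm12 and 0.20 in VP16 against engR. With every library left out in turn, 51 of 52 called named genes kept their call in noggin and retinoic acid against wild type, 0 of 10 with prdm12, 1 of 36 with engR, 12 of 26 between VP16 and prdm12 and 19 of 24 between VP16 and engR. Peak overlap was 5706 at a reciprocal 50% and 7804 for centres within 200 bp, within 1.5 times of 7497. Tests of genes near peaks (20, 5 and 50 kb) and of the higher-scoring part of each list were not run, for lack of matching gene coordinates and of scores. Depth limits low genes most: a count of 0 allows up to 3 reads per library.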

Other observations

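All tests and gene names in this part were chosen after their values were seen. Of 26 measured Hox genes, 24 rose with noggin and retinoic acid. Of 18 measured Hox genes of paralog groups 1 to 6, which pattern the hindbrain and anterior spinal cord, 18 rose, with a median log2 fold change of 7.02. Of 7 genes of groups 7 to 9, 6 rose (median 3.94), and hoxc13, a gene of the tail, had a log2 fold change of -1.26 and did not pass. Differences between the groups of Hox genes were not tested. In prdm12 caps 6 of 26 Hox genes were higher and 0 were called (median -0.23, camera p = 0.230 with an estimated correlation, 0.298 adjusted over 5 families), so a shift of Hox genes by prdm12 was neither shown nor excluded.

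Of 46 genes for receptors of neurotransmitters, the proteins by which neurons sense signals such as GABA, glycine, glutamate and acetylcholine, 8 fell between prdm12 and VP16. Between VP16 and noggin with retinoic acid no gene of any kind was called. In that comparison 33 receptor genes were lower and 13 higher, with a median log2 fold change of -0.744. The family did not pass there (camera p = 0.0387 with an estimated correlation, 0.124 adjusted over 5 families). The glycine receptor gene glra2 had 7.87 ± 3.08 normalized reads with noggin and retinoic acid, 219.9 ± 53.5 with prdm12, 263.0 ± 66.7 with engR and 4.5 ± 4.74 with VP16 (adjusted p = 0.00679 between VP16 and prdm12, limma). For the muscarinic acetylcholine receptor gene CHRM4 the levels were 43.3 ± 1.46, 480.005 ± 36.1, 303 ± 48.0 and 9.67 ± 7.16 (adjusted p = 0.0028), and for the nicotinic receptor gene chrna5 415 ± 13.6, 674 ± 140.2, 1034 ± 96.7 and 206 ± 15.8 (adjusted p = 0.0204). Between VP16 and prdm12, 9 receptor genes were higher without passing, and the family had a median log2 fold change of -1.63 (-1.39 after quantile normalization). A hypothesis is that the receptor family may move with the constructs as a group. It was tested by camera with an estimated correlation (p = 0.0272, or 0.119 adjusted over 5 families, which does not pass). Between VP16 and prdm12, 11 of 61 potassium channel genes, 8 of 32 sodium and calcium channel genes and 10 of 60 synaptic vesicle genes fell, but none of these families passed with an estimated correlation (p = 0.0698, 0.0712 and 0.127, adjusted p = 0.119, 0.119 and 0.159 over 5 families).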
